A study of Mus musculus with 24 samples.

How the data were processed

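Total RNA was extracted with Trizol and biotin-labelled by in vitro transcription, per the labels' protocols, and hybridised to Mu11k A and B oligonucleotide arrays. The deposited values are 1 linear intensity per probe set and array, made by the authors. The software that summarised and scaled them is not given in the sources used here. On every array the mean after trimming 2% of the values from each end lay between 500.3 and 501.4, so the deposited intensity values share a scale. They were not made in 1 way: all mock arrays hold only values of 0 or more, while 15.8% to 22.3% of the values on adenovirus A arrays and 26.8% to 34.2% on B arrays are below 0. A difference in how values were summarised therefore runs exactly along the groups. It can move probe sets that are dim in either group, and some that were bright in mock samples were below 0 on adenovirus arrays.

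Samples were grouped as mock or adenovirus by their labels, 6 each, and the number in the title joined the A and B arrays of 1 RNA sample. The descriptions of the mock B arrays name the A array, and the title and the probe sets of the table were followed. Mock and adenovirus share no numbers. The design, tests, gene lists, naming rule and most alternative settings were fixed before the data were examined, and the closing section names the settings chosen later.

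Within each table the 12 arrays were quantile normalized, floored at the larger of 20 and the 20th percentile of the table (23.4 for A, 20 for B) and put on the log2 scale. Control probe sets (55 per array type) and probe sets above the floor on fewer than 4 of 12 arrays were left out of the tests, which leaves 5814 on A and 5655 on B. Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, separately for each table, and adjusted together by the Benjamini-Hochberg method. The adjusted p threshold was 0.05, beside a log2 difference of 1 for a 2-fold change. A value at the floor has no order and no measured fold: where a whole group was at the floor the fold is given as a lower bound at that floor.

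Probe sets were named from a platform annotation and mouse gene symbols of the GRCm38.p6 assembly. On A, 5560 probe sets had 1 gene, 197 several and 827 none; on B, 2001 had 1, 27 several and 4567 none. Probe sets with several genes or none were tested without a name. Names ending in _f_at, _r_at, _i_at or _g_at were treated as uncertain, and some may be shared by related genes. Among the genes named below these include B2m, Actb, Gapdh, Col1a1, Cdkn1a and the main Mt1 probe set. No probe sequences were given, so the specificity of the other probe sets was not checked. Those ending in _s_at, such as the main ones of Ifit1, Gbp3 and Isg15, may match related genes too. The tests covered 5647 genes.

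The 34 gene lists were tested with camera (preset correlation 0.01, 1 probe set per gene, that with the highest mean, lists of at least 5 tested genes), with an estimated correlation and fry as alternatives. Of 1470 list members 1022 were named on the arrays. Percentiles of list medians used 10000 random lists matched on level. Genes named in the text were first the 12 largest rises and 12 largest falls among probe sets past the threshold with 1 symbol and fully separate groups. To these came up to 3 genes of each list by smallest p, or 1 where none passed, and 10 genes fixed in advance. Ifnb1, Lyz2 and Cd14 were added after their values were seen. Array measures were compared with an exact permutation test over 924 splits. Alternatives changed the normalization, floor, filter, test, adjustment and the samples included, and the closing section gives their effect. Scaling to a common median used, for each array, the median of its values above the floor, not of all its values. Figures used Python 3.11.15 and matplotlib 3.10.9.

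The pipeline was tested on simulated data with the means and spreads of the 11469 tested probe sets. Of 100 probe sets changed 2-fold 4% were called, of 100 changed 4-fold 48.0% were called, and 3.70% of the calls were false. With no list changed 0 lists were called, and with 1 list shifted 1 was. The simulated probe sets were drawn independently, from normal distributions and with no floor. These rates therefore do not describe correlated genes. In other divisions of the real samples into 2 groups of 6, a median of 3 lists passed the camera threshold.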

Results

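Gene expression was measured in primary mouse embryo fibroblasts, connective tissue cells taken from C57Bl/6 embryos of 13.5 days, that had been held in 0.2% serum for 48 hours to stop their growth. The cells were then either mock infected or infected for 16 hours with an adenovirus that lacks the E1 and E3 genes and carries LacZ, at a multiplicity of infection of 300. The comparison asks which host transcripts differ in arrested cells that received such a virus. There were 6 mock and 6 adenovirus RNA samples, each hybridised to an A and a B oligonucleotide array of the Mu11k set, 24 arrays in all. The A arrays held 6584 probe sets and the B arrays 6595, and the number of arrays limits the precision. Nothing in the labels states that samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

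Genes known to be induced by interferon had the highest median of the 34 gene lists. Of 39 tested members of the interferon list, 29 rose and none fell, 10 did not pass the threshold, and the median log2 difference was 3.18 (n = 6 per group). Adjusted over the list alone, 30 rose. Ifit1, which binds foreign RNA, rose by a log2 difference of 5.93 ± 0.44 (SE, n = 6 per group, limma adjusted p = 3.76e-06), with 2 of 6 mock arrays at the floor. Rises of 5.90 ± 0.40 for Ifi47, 5.74 ± 0.37 for Gbp3 and 5.65 ± 0.51 for Iigp1, all interferon-induced GTPases, each had 4 mock arrays at the floor, so their folds depend on where the floor was set.

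Other antiviral genes rose as well. Ifit3 rose by 4.27 ± 0.39, Isg15, a ubiquitin-like modifier, by 4.95 ± 0.76 (4.16 without mock 346), Usp18, which removes Isg15 from proteins, by 4.43 ± 0.43, and Rsad2, the antiviral protein viperin, by 4.31 ± 0.42 (SE, n = 6 per group). Irf7, a transcription factor of the interferon genes, rose by 3.24 ± 0.48 (adjusted p = 6.37e-04). The GTPase Igtp rose by 4.34 ± 0.46 with 3 mock arrays at the floor, and Cmpk2 by 5.12 ± 0.28 with 5, so the size for Cmpk2 depends on the floor as well. In each of these genes but Irf7 the rule for naming required all 6 adenovirus values to lie above all 6 mock values. Ifnb1, which encodes interferon beta itself, differed by -0.04 ± 0.47 (adjusted p = 0.970), and Irf3, which is needed to start its transcription, fell by 2.46 ± 0.41 with 5 of 6 adenovirus arrays at the floor (-3.29 and -1.64 with the floor at 0.5 and 2 times its value). The interferon list was past the threshold of limma's camera test (adjusted p = 6.91e-23), and adjusted p = 0.0183 with an estimated correlation. That p was 0.0605 without mock sample 346, an array pair that stood apart from the other mock samples, although 33 members then rose.

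**Figure D1:**
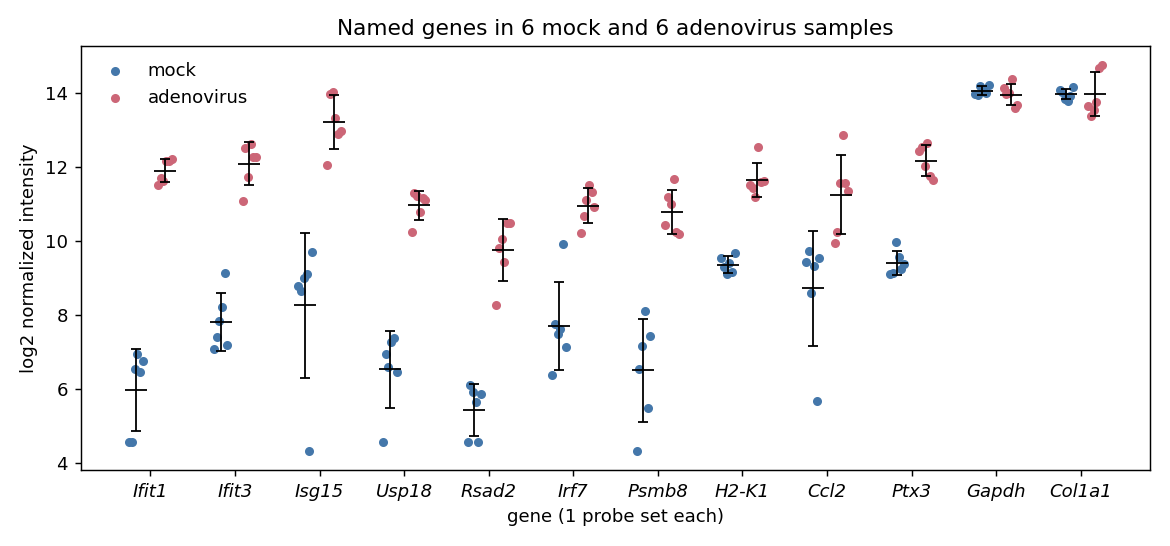
Log2 normalized intensity (vertical axis) of 12 named genes in the 6 mock and 6 adenovirus samples; points are samples, and black marks are the mean with SD. Isg15 had 1 mock sample at the floor. Gapdh and Col1a1 differed by -0.11 and -0.01, and Actb, which is not shown, by 1.55 (limma adjusted p = 0.435).

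Genes of antigen presentation rose as a group. Of 18 tested members, 11 rose and none fell; adjusted over the list alone, 12 rose and 1 fell. H2-K1, a class I histocompatibility gene whose probe set may be shared with related genes, rose by 2.28 ± 0.26 (SE, n = 6 per group, adjusted p = 8.28e-05), and the immunoproteasome subunits Psmb8 and Psmb10 by 4.28 ± 0.57 and 2.98 ± 0.64. B2m, the light chain of class I molecules, rose by 0.94 ± 0.29 (adjusted p = 0.0400), a call lost when arrays were scaled to a common median (0.76, or 1.36 relative to the median of all tested probe sets) and in 8 of 12 analyses that left out 1 sample (adjusted p up to 0.0819). The list was past the camera threshold (adjusted p = 2.33e-05), with adjusted p = 0.0300 with an estimated correlation and 0.0605 when mock 346 was also left out. Without mock 346 the list median was 1.59, against 1.37 with it, and 12 members rose.

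Among cytokines, chemokines and NF-kB targets, 10 of 44 tested members rose and none fell, and adjusted over the list alone 11 rose and 1 fell. Ptx3, a secreted pattern recognition protein, rose by 2.77 ± 0.28, the neutrophil chemokine Cxcl5 at least 14.0-fold, since all 6 mock arrays were at the floor (a log2 difference of 3.81, and 3.14 without adenovirus sample 0493), and the chemokines Ccl3 and Ccl2 by 3.42 ± 0.63 and 2.54 ± 0.68 (SE, n = 6 per group, adjusted p = 0.00246 and 0.0213). Cxcl5 rose by 4.81 and 2.81 with the floor at 0.5 and 2 times its value. Ccl3 had 5 mock arrays at the floor and rose by 4.10 and 2.58 at these floors. Its call was lost when arrays were scaled to a common median (1.99, or 2.59 relative to the median of all tested probe sets, adjusted p = 0.0726), and Ccl2 rose by 1.93 without mock 346. The camera adjusted p was 0.0250, and adjusted p = 0.939 with an estimated correlation. Without adenovirus sample 0493 it was 0.157. The list's median of 0.57 became -0.04 when arrays were scaled to a common median, which moved the median of all tested probe sets to -0.60. Relative to that median it was 0.56. Of the macrophage and white blood cell markers, 2 of 20 rose (Ptprc by 2.08 ± 0.34 and Adgre1 by 3.53 ± 0.71), and 1 fell, since Fcgr3 fell by 2.44 ± 0.64; the same counts were found adjusted over the list alone.

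Cell cycle genes were higher in part. Of 47 tested members of the E2F and G1/S list, 13 rose and 1 fell, and of 41 members of the G2/M and mitosis list, 11 rose and none fell; adjusted over the list alone, 14 rose and 1 fell in the first and 11 rose in the other. Mcm10, a DNA replication factor, rose by 2.73 ± 0.31 and Rbl1, a relative of the retinoblastoma protein, at least 3.37-fold, with all mock arrays at the floor. The log2 difference of Rbl1 was 2.64 and 0.75 with the floor at 0.5 and 2 times its value, so its size depends on the floor. Ccnb2, a mitotic cyclin, rose by 1.92 ± 0.38, Ect2, needed for cytokinesis, by 2.08 ± 0.35 and the condensin subunit Smc4 by 1.47 ± 0.28 (SE, n = 6 per group). Ccne1 rose by 1.18 ± 0.35 (adjusted p = 0.0345) and Ccna2 by 1.38 ± 0.45 (adjusted p = 0.0476), and both calls were lost under median scaling (0.66 and 0.84, or 1.26 and 1.44 relative to the median of all tested probe sets) and in 7 and 8 of 12 analyses that left out 1 sample (adjusted p up to 0.0720 and 0.104); that of Ccna2 was also lost with a floor of 0.5 times the value (adjusted p = 0.0530). Mybl2 fell by 3.02 ± 0.54, with 5 adenovirus arrays at the floor (-3.85 and -2.19 with the floor at 0.5 and 2 times its value). Camera gave adjusted p = 0.00311 and 3.94e-04 for the lists; with an estimated correlation these became adjusted p = 0.199 and 0.378.

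Among genes of the extracellular matrix, 11 of 63 rose and 3 fell, 12 and 3 adjusted over the list alone, with Lum up by 3.50 ± 0.51, Dcn by 2.59 ± 0.49 and Col6a2 by 1.77 ± 0.29 (SE, n = 6 per group). The list was not past the camera threshold (adjusted p = 0.126), nor with an estimated correlation (0.821, and 0.879 without mock 346). It was past it on the values as deposited (0.00301) and under median scaling (0.00740), where the list median was -0.05, or 0.55 relative to the median of all tested probe sets. Fry, which tests against no change, gave 0.0325. Of the actin cytoskeleton genes, 1 of 46 rose and 7 fell, 1 and 9 adjusted over the list alone, and the list also missed the threshold (adjusted p = 0.196). Itga5, a fibronectin receptor chain, fell by 3.66 ± 0.72 and the adhesion protein Vcl by 2.77 ± 0.63, with 2 and 1 adenovirus arrays at the floor. Myh11, a smooth muscle myosin, fell by 3.10 ± 0.26 with 5 adenovirus arrays at the floor (-3.93 and -2.25 with the floor at 0.5 and 2 times its value).

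The 12 probe sets with the largest falls included Entpd2, Actn3, Atp5d, Cops4 and Slc44a4, each with all 6 adenovirus arrays at the floor. With mock 346 included, their mean mock level was at least 40.5-fold, 34.9-fold, 20.7-fold, 19.3-fold and 17.6-fold above the floor. Without mock 346 the log2 differences moved from -5.34, -5.13, -4.37, -4.27 and -4.14 to -4.92, -4.65, -3.92, -4.59 and -3.74. Fabp3 fell by 5.44 ± 0.45 and Arhgef2 by 4.21 ± 0.40, each with 5 adenovirus arrays at the floor, and Rhob, a small GTPase, fell by 4.46 ± 0.61 with 2 (SE, n = 6 per group). With the floor at 0.5 and 2 times its value the differences were -6.27 and -4.61 for Fabp3 and -5.04 and -3.29 for Arhgef2, so these sizes are set in part by the floor. Of the 935 lower calls, 171 had every adenovirus array at the floor, and 467 (49.9%) had deposited values below 0 on at least 3 adenovirus arrays. No mock array held a value below 0, whereas every adenovirus array did. Entpd2, Actn3, Atp5d, Cops4, Slc44a4 and Arhgef2 were below 0 on all 6 adenovirus arrays, Fabp3 on 5 and Rhob on 2. Mean mock log2 levels of these genes ran from 8.59 (Cops4) to 10.25 (Fabp3). Their falls cannot be told apart from the difference in how the groups' values were made.

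No other list of the 34 passed the camera threshold in the main analysis. Rises and falls, in that order, were 0 and 1 of 11 in innate sensing, 0 and 1 of 18 in p53 targets, 1 and 1 of 22 in apoptosis regulators, 2 and 0 of 30 in heat shock, 1 and 2 of 31 in ER stress, and 2 and 1 of 36 in oxidative stress and metallothioneins. They were 5 and 2 of 39 in proteases and inhibitors, 3 and 4 of 39 in immediate early genes, 4 and 1 of 39 in quiescence and cyclin genes, 3 and 2 of 49 in growth factor, TGF-beta and Wnt genes, 2 and 2 of 22 in sterol and lipid genes, and 1 and 3 of 27 in glycolysis and hypoxia. Mitochondrial respiration had 2 and 6 of 58, ribosomal proteins 2 and 0 of 44, translation and ribosome biogenesis 2 and 2 of 57, the proteasome and ubiquitin genes 4 and 1 of 42, adenovirus entry factors 0 and 0 of 15, and control genes 1 and 0 of 14. Adjusted over the list alone the rises ranged from 0 to 5 and the falls from 0 to 5 in these lists. Cdkn1a, a p53 target, differed by -0.63 ± 0.48 (adjusted p = 0.398), and the metallothionein Mt1 by -3.11 ± 1.06 (adjusted p = 0.0604) with adenovirus samples 1168 and 1169 at the floor. Without 1168, and without 1169, the Mt1 difference was -2.39. It passed the threshold under median scaling (-3.36, adjusted p = 0.0230), with the floor doubled (-2.77, adjusted p = 0.0410) and without 0183 or 0493 (adjusted p = 0.0467 and 0.0263). Another Mt1 probe set fell by 3.59 ± 0.56 (adjusted p = 8.52e-04), with 5 adenovirus arrays at the floor. Actb, fixed in advance, differed by 1.55 (adjusted p = 0.435). Its level was 6.26 and 5.99 in adenovirus samples 1168 and 1169 and 11.4 to 13.0 in the other adenovirus samples. Mock samples lay at 7.25 to 10.9.

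Markers of other cell types moved in both directions. Rises and falls were 3 and 1 of 11 for endothelial cells, 1 and 2 of 12 for epithelial cells, 1 and 3 of 22 for muscle, 2 and 2 of 16 for neural cells, 1 and 1 of 9 for red cell precursors, 1 and 0 of 8 for adipocytes, 1 and 2 of 8 for cartilage and bone, and 1 and 0 of 8 for hepatocytes. Adjusted over the list alone the counts were 4 and 1, 1 and 3, 1 and 3, 2 and 2, 2 and 2, 1 and 1, 1 and 4, and 1 and 0. The endothelial receptor Tek rose by 2.65 ± 0.25, with 5 mock arrays at the floor. With the floor at 0.5 and 2 times its value, Tek rose by 3.21 and 1.65. The keratin Krt14 had all adenovirus arrays at the floor, its mock level being at least 12.8-fold higher with mock 346 included. Its log2 difference was -3.68, and -3.32 without mock 346. With the floor at 0.5 and 2 times its value it was -4.68 and -2.68. Another Krt14 probe set, at the floor on 5 mock arrays, differed by 0.75 ± 0.59 (adjusted p = 0.410).

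**Figure D2:**
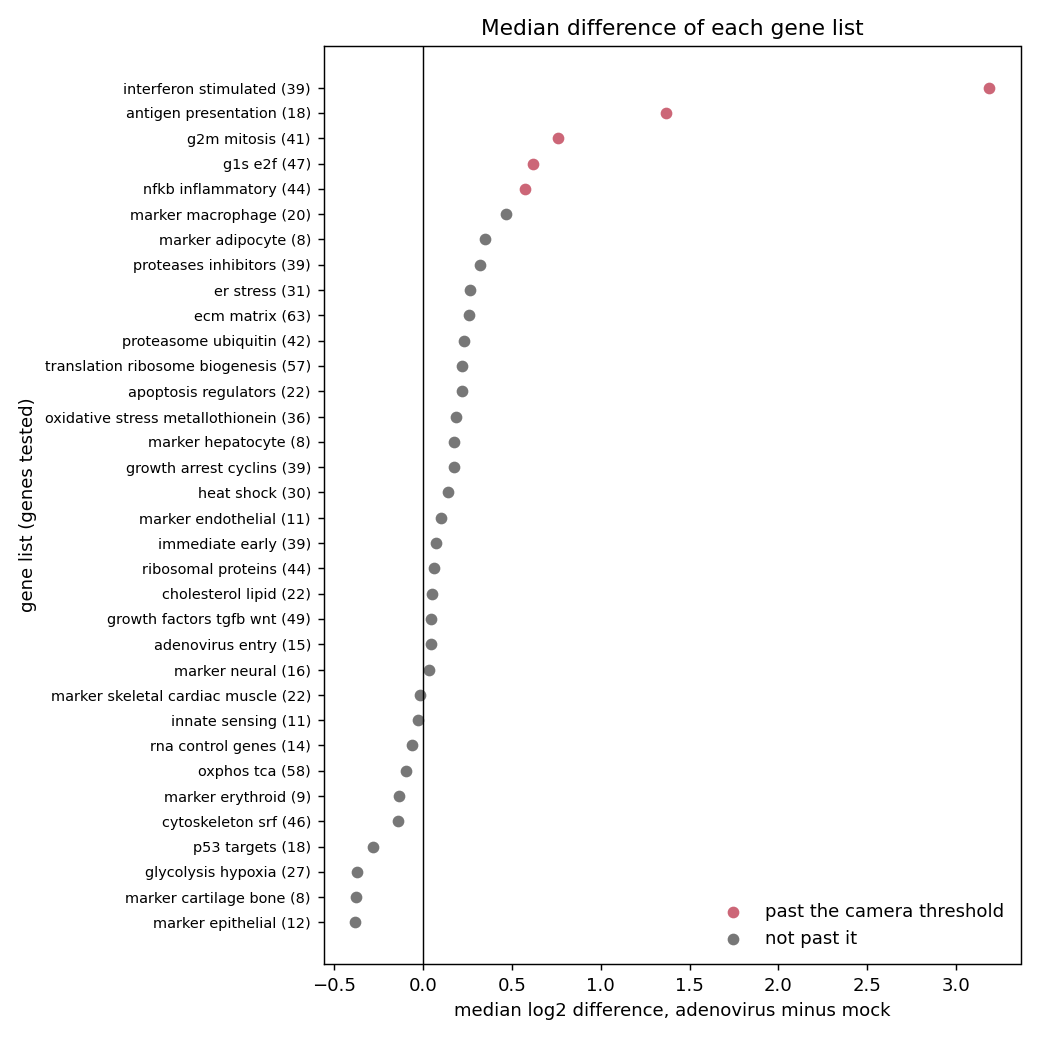
Median log2 difference, adenovirus minus mock (horizontal axis), of the 34 gene lists, with the number of genes tested in brackets; red points are the 5 lists past the camera threshold. The interferon list lies at 3.18 and antigen presentation at 1.37.

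Over both arrays, 11469 probe sets were tested with limma and 1986 were past adjusted p of 0.05, 1051 higher and 935 lower with adenovirus, of which 1863 changed at least 2-fold (983 higher, 880 lower). The groups did not overlap for 1128 probe sets (9.84%), where chance gives 0.216%. The higher share of calls was 52.9%. It was 12.9% when arrays were scaled to a common median of the values above the floor and 30.1% on the values as deposited. The balance of rises and falls was therefore set by the scaling. More values lay at or below the floor in adenovirus than in mock samples (means of 25.0% against 14.7% on A, 36.0% against 11.1% on B). Scaling on the median of all values was not run. The deposited values of the groups were made differently, and this cannot be told apart from infection.

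Some measures of array quality differed between groups. The share of probe sets below 0 was 18.4% ± 2.65 on adenovirus A arrays and 30.8% ± 2.76 on B arrays (SD, n = 6) and 0 on mock arrays, with an exact two-sided permutation p of 0.00216 (adjusted p = 0.0141 over 26 measures). The median B intensity was 163 ± 40.4 in mock and 98.0 ± 23.7 in adenovirus samples (SD, n = 6, exact permutation p = 0.00433, adjusted p = 0.0225). The mean correlation within the group on A was 0.810 ± 0.130 in mock and 0.887 ± 0.0140 in adenovirus samples (SD, n = 6, exact permutation p = 0.00866, adjusted p = 0.0375), a difference that mock 346 makes, as the correlations without it below show. The ratios of 3' to 5' probe sets of Actb, Gapdh and Tfrc, the 18S ribosomal RNA signal and the spiked bacterial transcripts did not pass the adjusted threshold. Mock 346 correlated with the other mock A arrays at r of 0.521 to 0.572 across probe sets, where other mock pairs reached 0.922 to 0.964 and adenovirus pairs 0.832 to 0.971. Without it 2711 probe sets were called.

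**Figure D3:**
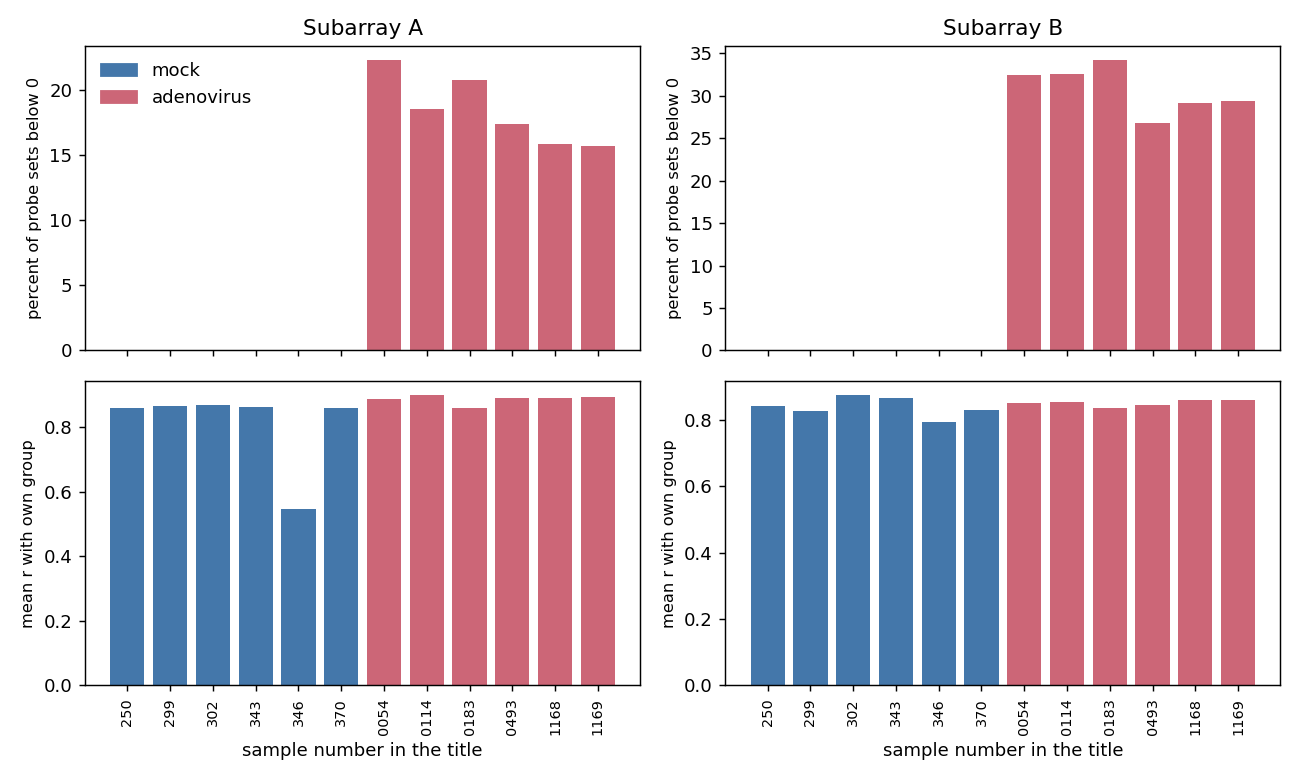
Percent of probe sets below 0 (upper bars) and mean correlation with the other arrays of the same group (lower bars) for each sample on subarrays A and B. Mock arrays are at 0 in the upper panels, and mock 346 has the lowest mean r on A, 0.545.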

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

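The tests on the interferon list, on the lower calls and on the rank correlation of mock 346 were chosen after the results were seen. The correlation of 346 between A and B and all counts of splits were set before. Of 276 groups of 6 values, 52 had a highest or lowest sample whose gap to the nearest other, over the whole range, passed the 95% critical value of Dixon's test, where chance gives about 1 in 20 groups; 21 of these were mock 346. A ratio of 1 means that the other 5 values were all at the floor.

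Mock 346 lay lowest for the mean correlation with its group on A (ratio 0.965) and for the share of values at or below the floor on A (0.775), and highest for the median intensity on A (0.772), the 18S signal on A (0.878) and the Tfrc 3' to 5' ratio on A (0.780). Its Actb 3' to 5' ratio on B was lowest (0.802). Among genes it was lowest for Isg15 (0.805), Fabp3 (0.863), Rps26 (0.860), Ccl2 (0.722), Acan (0.688), Krt19 (0.685) and Serpinf1 (0.638), and highest for Iigp1 (0.717), Entpd2 (0.714), Actn3 (0.747), Ect2 (0.631), Dhcr7 (0.702), Ube2l6 (0.793), Fcgr3 (0.769) and Krt14 (0.705).

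Mock 346 stood apart most on A, but on B as well. There 0.318% of its values were at or below the floor, against 10.7% to 18.3% in the other mock samples. Its B median was highest at 233.8 (others 124.8 to 180.1), and so was its 18S signal. Its mean correlation with the group on B was lowest at 0.793 (others 0.827 to 0.873). Another RNA in the tube was predicted to make its deviations from the other mock samples correlate between A and B. Over 348 genes on both, r was 0.0363, below the highest of the other mock samples at 0.144. Different probe sets were compared, and no sample had a known shared deviation to show what r it would give. The low r therefore does not decide this. A compressed range of the A array would keep the order of the deposited values, but the highest rank correlation of 346 with another mock sample was 0.598, where those samples reached 0.934 to 0.968 among themselves, and 0.548 against 0.886 to 0.943 over probe sets above the median. This argues against compression as the whole cause. Another RNA, or a failed hybridisation of either array or both, stays open, and no biological explanation was tested.

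The interferon list rose by a median of 3.18. A difference in how the groups' values were made would move other genes of like level too, but the highest median of 10000 random lists matched on level was 0.76, which argues against it as the whole cause, though the lists were matched on level alone, and the median was 3.01 without mock 346. White blood cells in the infected cultures could add such transcripts. Macrophage markers with a low mock level had a median of 0.46 over 8 genes, against 3.18 for the interferon list. Their interval of -0.40 to 3.53 overlapped the interferon list's 2.11 to 3.47. With 8 genes that interval is the full range, and its upper end is Adgre1 alone, so the overlap does not decide this. White blood cells cannot be told apart from a response of the fibroblasts by this test. Ptprc and Adgre1 rose by 2.08 and 3.53 and Fcgr3 fell by 2.44, while the abundant Lyz2 and Cd14, chosen after their values were seen, differed by 0.57 and 0.44 without passing the threshold (limma adjusted p = 0.296 and 0.462), where a high level in mock samples would hide a small share. A response to the virus, the biological explanation the design names, stays open.

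Of the 935 lower calls, 467 had values below 0 on at least 3 adenovirus arrays, which the selection for low adenovirus values itself favours. If they came from how the groups' values were made, another probe set of the same gene with a different accession need not be lower. It was lower for 36 of 67 genes with a lower call, 53.7% (exact 95% interval 41.1 to 66.0), against 45.3% of 318 uncalled genes; for higher calls 61 of 84 (72.6%, interval 61.8 to 81.8) had the other probe set also higher, against 54.7% of uncalled genes. By Fisher's exact test the share differed between lower and higher calls (p = 0.0178) and between higher calls and uncalled genes (p = 0.00401), and p was 0.227 for lower calls against uncalled genes; this is consistent with a technical origin for some lower calls, but uncalled genes also lean higher and different accessions may share probes. A fall of some transcripts after infection stays open.

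For the other samples, adenovirus 0114 was highest for Fabp3, Myb and Mybl2 (ratio 1 each) and Gata1 (0.649), and lowest for Vcl (0.646). Adenovirus 0183 was highest for Irf3, Myh11, Ptprb and Sox10 (1 each) and lowest for the mean correlation on A (0.711). Adenovirus 0493 was highest for H2-K1 (0.672), Ccl3 (0.645), Egf and Eif6 (1 each) and lowest for Igfbp2 (0.691). Adenovirus 1168 was highest for Grb10 (0.822) and Arhgef2 (1), and 0054 lowest for Ube2l6 (0.651). Mock 250 was highest for Cmpk2 (1) and the Cre spike on B (0.684) and lowest for Usp18 (0.676). Mock 299 was lowest for Irf3 (0.811), Mmp13 (0.793) and Cdkn1a (0.878). Mock 302 was highest for Casp4 (0.669) and lowest for the Gapdh 3' to 5' ratio on B (0.644), mock 343 highest for Ccl3 (1) and lowest for Uqcrb (0.705), and mock 370 highest for Gstt1 and Tek (1 each) and Cdh1 (0.876).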

How the results depend on the processing

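The alternatives on filters above the floor on all arrays, on like-level spread, on averaging 1168 and 1169, and those that join 346 with another choice were chosen after seeing the data, as were the rank test, trend and within-array adjustment for the 2-fold count and the deposited scale for the lists. Leaving out 1 sample at a time moved the called probe sets from 1492 to 2711, the highest without mock 346, and the lists past the threshold from 4 to 5; the NF-kB list ranged from adjusted p 0.00500 to 0.157, past the threshold except without adenovirus 0493. Scaling to a common median gave 3626 calls (468 higher, 3158 lower), and 3398 changed at least 2-fold (407 higher, 2991 lower). The values as deposited gave 1854 lower calls, 1805 of them at least 2-fold, and 10 lists. These scalings lower the median difference of all probe sets to -0.60 and -0.28. Gstt1 turned to -0.47 and -0.0647 and Pax6 to -0.71 and -0.38 under them, no longer past the threshold. Requiring values above the floor on 9 of 12 arrays gave 534 lower calls, and 1241 at least 2-fold (489 lower), from fewer probe sets. The exact rank test gave 560 lower at least 2-fold, and array weights 3282 calls (1709 higher, 1573 lower); the cause was not tested.

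Lists short of the threshold passed camera in some settings: epithelial markers under median scaling (0.0183) and on the values as deposited (0.0107), and heat shock, translation and proteasome genes on the latter (0.0451, 0.0482 and 0.0473). Glycolysis did so with values above the floor on all 12 arrays (0.0324). Fry, which tests against no change, gave 0.0257 for epithelial and 0.0134 for cartilage and bone markers. With an estimated correlation camera gave 0.562 for both, 0.939 for heat shock, translation and proteasome genes and 0.750 for glycolysis.

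With an estimated correlation 2 lists remained past the threshold; the adjusted p was 0.939 for NF-kB, 0.199 for G1/S and 0.378 for G2/M. For NF-kB it was 0.129 with fry and 0.0774 with the mean of a gene's probe sets. With 346 also left out 0 lists passed with camera, 3 being at unadjusted p under 0.05, with adjusted p 0.0605 for interferon and for antigen presentation, 0.879 for NF-kB, 0.160 for G1/S and 0.549 for G2/M, at unadjusted p of 0.00356, 0.00323, 0.362, 0.0142 and 0.113; the cause was not tested. Probe sets above the floor on all 12 arrays gave 933 calls (551 higher, 382 lower) and 775 at least 2-fold (463 higher, 312 lower). With 346 left out and the other 11 arrays above it, 1032 were at least 2-fold (621 higher, 411 lower). Fewer probe sets enter these. A further limit on the calls, a difference beyond 3 median absolute deviations, left 221 (97 higher, 124 lower), all at least 2-fold. Of 448 other checks on named probe sets 410 kept their side of the threshold, 31 weakened, 3 passed it and 4 turned sign; of 1344 with 1 sample left out, 1209 kept it. No paired analysis was possible because mock and adenovirus samples share no title numbers. Dim probe sets are limited by the floor.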

Other observations

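The single genes here are from lists that did not pass the camera threshold, or from no list. Sfrp2, a Wnt antagonist, rose by 3.39 ± 0.46 and the receptor Pdgfra by 2.68 ± 0.51, while Inhba, a subunit of activin, fell by 2.20 ± 0.30 (SE, n = 6 per group, limma adjusted p = 3.09e-04, 0.00325 and 3.00e-04). Serping1, an inhibitor of complement C1, rose by 1.97 ± 0.45 and Ube2l6, the conjugating enzyme of Isg15, by 2.64 ± 0.35 (adjusted p = 0.00930 and 2.46e-04), both from probe sets whose names mark them as shared with related genes. Apod, a lipocalin, rose by 5.52 ± 0.67 with 3 mock arrays at the floor, from another such probe set.

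The counts of splits were set before their results were seen. Of 100 splits of the 12 samples, drawn from 462 and the real one included, 1 gave as many called probe sets as the real 1986, the highest other being 441. Again 1 gave as many changed at least 2-fold (1863, highest other 437), so no other drawn split reached either count. The real split is also the split in how the values were made, and the samples may not be separate cultures. These counts therefore do not show that infection is the source. For the number of lists past the preset-correlation threshold chance is not excluded, since 22 of 100 splits gave 5 or more, and the highest other gave 10. Singly, 1 of 100 splits gave a camera p as small as the real one for the interferon list (2.03e-24, smallest other 3.15e-18) and 1 for antigen presentation (1.37e-06, smallest other 2.62e-06). For G1/S 3 splits did (3.66e-04, smallest other 2.06e-04), for G2/M 5 (3.48e-05, smallest other 1.49e-06) and for NF-kB 39 (0.00367, smallest other 2.40e-06). Chance is not excluded for G2/M and NF-kB. For G1/S another split also gave a smaller p than the real one, so chance is not firmly excluded there either.

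Adenovirus samples 1168 and 1169, whose numbers are adjacent, correlated at r of 0.971 on A and 0.947 on B across probe sets, where the next highest adenovirus pair reached 0.921 and 0.882; averaged into 1 sample, 1692 probe sets were called. A B2 repeat probe set on both arrays, MUR_b2_at, rose by 1.34 ± 0.33 on A and 1.13 ± 0.36 on B (SE, n = 6 per group, limma adjusted p = 0.0134 and 0.0443), the B call being lost under median scaling (0.92, or 1.52 relative to the median of all tested probe sets, adjusted p = 0.0876). Another B2 probe set, MURINE_B2_at, differed by -0.05 and 0.19, with adjusted p of 0.906 and 0.638. The B1 repeat probe set MURINE_b1_at fell by 1.06 ± 0.29 on A (adjusted p = 0.0222) and differed by -0.53 ± 0.30 on B (adjusted p = 0.254).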
